A study of Mus musculus with 58 samples.

How the data were processed

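RNA was measured in 58 mouse samples in 18 groups. Per the labels, total RNA was extracted with TRIzol and a clean-up kit, and libraries were made with the QuantSeq 3' mRNA-Seq FWD protocol, which yields reads from the 3' end of polyadenylated transcripts. The authors named Trim Galore for trimming, STAR for alignment and the GRCm38 genome build, while versions, the counting tool and the annotation release are not given in the sources used here. The deposited values are counts, in 3 tables of 25965 gene rows each, not normalized, with 18 libraries for the amino acid experiment, 16 for the inhibitor experiment and 24 for the knockout experiment. Every per-sample column was used. Of the gene IDs, 24990 were found in GENCODE M21, and 56 rows had no Ensembl ID. Rows of mitochondrially encoded genes held only 0 in the inhibitor and knockout tables, so those genes were measured in the amino acid table alone.

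Groups were taken from the labels, and each table was tested only within itself. Total counts per library were 2068713 to 5170604 in the amino acid experiment, 2035711 to 3760377 in the inhibitor table and 1709951 to 3039130 in the knockout table. Genes with low counts were removed with filterByExpr by group, and normalization used trimmed means of M values (TMM). All groups measured together entered 1 edgeR quasi-likelihood model with a coefficient per group and a common trend of spread, and contrasts gave 22 comparisons. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in its table. The SE was computed as the absolute log2 fold change divided by the square root of the F statistic. CPM used the TMM-scaled library sizes. Comparisons by genotype tested the difference between the effect in Ph2 and that in Ren. The biological coefficient of variation was 0.11 in the amino acid table, 0.121 in the inhibitor table and 0.113 in the knockout table. Between libraries of a group, the chi-square per degree of freedom of their counts was at least 1.65, 2.38 and 2.39 in these tables, above the value of 1 for repeated sequencing of 1 library.

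The design, the alternatives and 28 gene lists were fixed before the data were examined. The lists hold osteoclast genes, repressors of osteoclast formation, macrophage and monocyte genes, serine synthesis and folate one-carbon genes, ATF4 and amino acid response genes, aminoacyl-tRNA synthetases, cholesterol synthesis genes, NRF2 and glutathione genes, cell cycle genes, p53 targets, interferon-stimulated genes, inflammatory genes, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes, glycolysis genes, purine synthesis genes, methyl cycle and chromatin methylation genes, unfolded protein response genes, V-ATPase (vacuolar proton pump) genes, progenitor genes, sex-linked genes, and markers of neutrophils, dendritic cells, B cells, T and NK cells, erythroid cells, stromal cells and osteoblasts, and mast cells and basophils. Of 463 members, 452 were found by symbol and 9 by Ensembl ID. A list with at least 3 tested members was tested with limma's camera on log2 CPM (prior count 3) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members called were counted by the test over all genes and adjusted over the list alone. Sets of up to 200 genes with the smallest p among those called and changed over 2-fold by RANKL were carried to the other tables with the same test.

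Genes are named by a rule fixed with the design. It takes, per comparison, the 8 genes with the largest change up and the 8 down among called genes with a mean of at least 10 CPM whose libraries do not overlap between groups (no overlap condition by genotype), up to 4 members with the smallest p of each list described, and 16 fixed genes. Fancd2 in the addition of Pyr to Ph2 cells fell outside the rule. A fold against a group without counts was computed with a floor of 3 counts over the group.

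The tests were tested on simulated data with the depth of the real libraries, 6 sets for each of 4 comparisons. The spread was the trend fitted over genes of similar level, and the mean profile was pooled over all groups. Spread of single genes around that trend and correlation between genes were left out, so shares in the real data may differ. In each set 200 genes were changed, besides the members of a raised list. Where far more genes change, the threshold on p is less strict, so the shares found need not hold there. Changes of 2-fold were found in 78.6% for arginine withdrawal, 79.3% for SHIN1, 63.7% for Ph2 against Ren with RANKL and 48.3% for withdrawal by genotype, and changes of 1.5-fold in 45.6%, 42.1%, 43.0% and 15.7%. False calls made up 4.01%, 4.85%, 4.39% and 5.73% of the calls.

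Alternatives were the size factors of DESeq2 (RLE), no filter on low counts, the DESeq2 Wald test, a fit of only the groups compared, leaving out each library in turn, the title number as a replicate block in the amino acid table, the estimated correlation, sets of 100 genes, an adjusted p under 0.01 for the formate overlap, and only genes called in both systems for the correlation. Title numbers were checked for pairing by correlating the deviations of libraries from their group means. Over 45 pairs with the same number r had a median of -0.00446 and a highest value of 0.216, and 6 of 18 libraries lay closest to 1 of their own number, so no block was used. For the formate overlap, the planned simulation without any effect (overlap 0 in each of 20) gives no chance value, since a test that controls false calls leaves almost no overlap there in advance. Other splits of the samples were counted in full, or 100 were drawn for comparisons by genotype. The work used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.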

Results

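Gene expression was measured by 3' mRNA sequencing in 58 mouse samples from 3 experiments on osteoclast formation. Osteoclasts are the multinucleated cells that resorb bone, and they form from myeloid precursors that receive macrophage colony-stimulating factor (MCSF), which keeps the precursors alive, and RANKL, the cytokine that starts osteoclast differentiation. The amino acid experiment held 18 libraries of bone marrow derived cells given MCSF and RANKL, with 24 h in their titles. The medium was full or lacked arginine, cysteine, glutamine, proline or tyrosine, with 3 libraries per medium. The inhibitor experiment held 16 libraries of bone marrow derived cells in 4 groups of 4, which received MCSF alone, MCSF with RANKL, these with SHIN1 (an inhibitor of serine hydroxymethyltransferase, the enzyme that passes a one-carbon unit from serine to folate), or these with SHIN1 and formate, a one-carbon donor. The knockout experiment held 24 libraries of a HoxB8 myeloid progenitor line, in which expression of the HoxB8 transcription factor keeps progenitors dividing until it is withdrawn. Its 8 groups of 3 crossed a control genotype labelled Renilla (Ren) and a genotype labelled Ph2 and PHGDH KO with MCSF, MCSF and RANKL, MCSF and RANKL without serine and glycine, and the latter with an addition labelled Pyr. Phgdh encodes phosphoglycerate dehydrogenase, the first enzyme of serine synthesis.

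Total counts per library ranged from 2068713 to 5170604 in the amino acid experiment, from 2035711 to 3760377 in the inhibitor experiment and from 1709951 to 3039130 in the knockout experiment. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Values are given as log2 fold change ± SE with the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test, or as counts scaled by library size (CPM) ± SD over the libraries of a group. A gene is said to rise or fall where the adjusted p was under 0.05, which means higher or lower than in the group compared. Where no gene differs, a share of about 0.05 of the genes tested still has an unadjusted p under 0.05. List tests used camera with a preset correlation, its adjusted p being over the lists of a comparison.

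The amino acid comparisons asked how RANKL-treated cells without 1 amino acid differ from those in full medium. The titles do not say whether 24 h times RANKL, the withdrawal or both. No group without RANKL was measured in this experiment, so loss of an expressed gene and lack of its induction cannot be told apart. Without arginine, genes of osteoclast function fell and genes of the amino acid stress response rose. Nfatc1, the transcription factor that drives osteoclast differentiation, went from 408 ± 96.9 CPM in full medium to 46.2 ± 3.09 CPM (n = 3 each; log2 fold change -3.14 ± 0.16, adjusted p = 1.5e-13). Acp5, which encodes tartrate-resistant acid phosphatase, fell 9.79-fold (log2 fold change -3.29 ± 0.19, adjusted p = 1.44e-12). Ocstamp and Dcstamp, needed for fusion of precursors, had log2 fold changes of -4.07 ± 0.42 and -3.40 ± 0.28. Prdm1 (-4.10 ± 0.17) and Jdp2 (-3.09 ± 0.15), both transcription regulators that promote osteoclast formation, and Mmp9 (-2.61 ± 0.13), a matrix protease, fell too. Of the 20 osteoclast genes tested, 15 fell and 1 rose, the same numbers when adjusted over the list alone (camera, adjusted p = 1.22e-14). All 6 repressors of osteoclast formation rose, also when adjusted over the list alone, among them Mafb (1.22 ± 0.13), Irf8 (1.18 ± 0.13) and Id2 (1.22 ± 0.12), with adjusted p = 2.87e-05, and adjusted p = 0.0679 with an estimated correlation.

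On the side of raised genes, Trib3, a pseudokinase induced by the transcription factor ATF4, rose 52.5-fold without arginine, from 3 ± 0.222 to 161 ± 7.63 CPM (n = 3 each; log2 fold change 5.71 ± 0.18, adjusted p = 2.16e-17). Chac1, a glutathione-degrading enzyme (4.01 ± 0.26), Nupr1 (3.45 ± 0.19), Ddit3, which encodes the stress factor CHOP (2.97 ± 0.14), and the asparagine synthetase gene Asns (2.87 ± 0.10) rose with it. In all, 23 of the 26 ATF4 and amino acid response genes tested rose and none fell, also over the list alone (camera, adjusted p = 1.68e-18). The serine synthesis genes Phgdh (3.67 ± 0.36), Psph (2.23 ± 0.20) and Psat1 (0.84 ± 0.09) rose, as did the mitochondrial folate genes Shmt2 (1.09 ± 0.13) and Mthfd2 (1.38 ± 0.13). Of the aminoacyl-tRNA synthetases, which charge tRNAs, 12 of 20 rose and 4 fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.000857). NRF2 and glutathione genes rose in 15 of 20 and fell in 1 (raised in 16 over the list alone), with Gclm at 1.16 ± 0.14 (camera, adjusted p = 2.7e-06, and adjusted p = 0.0679 with an estimated correlation). Over all 10115 genes tested, edgeR called 1681 raised and 1437 lowered. The share of counts on mitochondrially encoded genes was 2.19% ± 0.083 (SD, n = 3) without arginine and 3.12% ± 0.115 in full medium.

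Without cysteine the same kinds of genes moved, and cell cycle genes fell as well. Trib3 rose 104-fold (log2 fold change 6.70 ± 0.18, adjusted p = 2.64e-19), Ddit3 had a log2 fold change of 3.37 ± 0.14 and Slc7a11, the cystine importer, one of 3.63 ± 0.15. Gdf15, a stress-induced secreted factor, rose (4.93 ± 0.21), as did Asns (3.35 ± 0.10) and Phgdh (4.46 ± 0.34). Of the 26 ATF4 and amino acid response genes, 25 rose, also over the list alone (camera, adjusted p = 3.19e-15). Nfatc1 (log2 fold change -3.31 ± 0.16, adjusted p = 1.06e-14), Acp5 (-3.79 ± 0.20), Prdm1 (-4.38 ± 0.17) and Jdp2 (-3.16 ± 0.15) fell. In all, 15 of the 20 osteoclast genes were lower and 3 higher, also over the list alone (camera, adjusted p = 2.3e-06). All 6 repressors rose, also over the list alone, Irf8 by 1.99 ± 0.13 (adjusted p = 0.000297, and adjusted p = 0.086 with an estimated correlation). All 27 cell cycle genes fell, also over the list alone, including Top2a (-3.58 ± 0.14), the DNA topoisomerase of dividing cells, and Birc5 (-3.93 ± 0.16), with adjusted p = 1.14e-19. NRF2 and glutathione genes rose in 18 of 20 and fell in 1, also over the list alone, with Gstm1 at 1.95 ± 0.12 (camera, adjusted p = 1.1e-08). In the folate group Dhfr (-2.34 ± 0.16), Tyms (-2.17 ± 0.16) and Shmt1 (-2.88 ± 0.24), which serve nucleotide synthesis, fell while Mthfd2 rose (1.43 ± 0.13). The edgeR test called 2812 genes raised and 2775 lowered, and the mitochondrially encoded share of counts was 1.85% ± 0.010 (SD, n = 3).

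Without glutamine, Trib3 (log2 fold change 5.45 ± 0.18, adjusted p = 7.8e-17), Gdf15 (3.45 ± 0.22), Atf5 (3.43 ± 0.20), Asns (2.11 ± 0.10) and Phgdh (3.12 ± 0.38) rose. Psat1 (-0.53 ± 0.10), whose enzyme uses glutamate as amino donor, and Shmt1 (-2.18 ± 0.21) fell. Of the ATF4 and amino acid response genes 22 of 26 rose and 1 fell, also over the list alone (camera, adjusted p = 8.08e-09). Acp5 (log2 fold change -3.92 ± 0.19, adjusted p = 4.52e-14), Nfatc1 (-3.13 ± 0.16), Dcstamp (-5.80 ± 0.37) and Prdm1 (-3.82 ± 0.16) fell among 15 lowered and 3 raised of 20 osteoclast genes, also over the list alone (camera, adjusted p = 8.08e-09). All 6 repressors rose, also over the list alone (adjusted p = 0.000101, and adjusted p = 0.0821 with an estimated correlation), with Irf8 at 1.87 ± 0.13. Of 27 cell cycle genes 26 fell, also over the list alone, Top2a at -2.51 ± 0.13 (camera, adjusted p = 4.5e-17). Markers of neutrophils were higher in 11 of 12, also over the list alone, with S100a9 at 0.82 ± 0.15 and Camp at 0.92 ± 0.14 (camera, adjusted p = 0.00138, and adjusted p = 0.177 with an estimated correlation). Dendritic cell markers were lower in 5 of 6, with the same number lower and 1 higher over the list alone (adjusted p = 0.0107, and adjusted p = 0.177 with an estimated correlation). In total 2643 genes rose and 2334 fell, and mitochondrially encoded genes took 2.13% ± 0.319 of the counts (SD, n = 3).

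Without tyrosine, Trib3 rose 53.6-fold (log2 fold change 5.74 ± 0.18, adjusted p = 1.65e-17), with Ddit3 (3.02 ± 0.14), Nupr1 (3.36 ± 0.19), Asns (2.60 ± 0.10) and Phgdh (3.44 ± 0.36). Of 26 ATF4 and amino acid response genes 22 rose (22 over the list alone, with 1 lowered; camera, adjusted p = 7.45e-16). Acp5 went from 388 ± 106 to 26.1 ± 2.89 CPM (n = 3 each; log2 fold change -3.87 ± 0.19, adjusted p = 9.14e-14). Nfatc1 (-3.03 ± 0.15), Ctsk, the collagen-degrading cathepsin K (-2.26 ± 0.15), and Ocstamp (-5.08 ± 0.46) fell as well, among 15 lowered and 1 raised of 20 osteoclast genes, also over the list alone (camera, adjusted p = 1.84e-14). All 6 repressors rose, also over the list alone (adjusted p = 0.000225, and adjusted p = 0.0912 with an estimated correlation). Cell cycle genes fell in 21 of 27, also over the list alone, with Ube2c at -1.78 ± 0.12 (camera, adjusted p = 1.78e-09). The edgeR test called 1843 genes raised and 1563 lowered, and mitochondrially encoded genes took 2.64% ± 0.160 of the counts (SD, n = 3). For comparison, 12 of the 27 cell cycle genes fell and 4 rose without arginine, where camera gave adjusted p = 0.054.

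Leaving out proline changed few genes past the threshold, while 1024 of 10115 had an unadjusted p under 0.05. Asns rose 2.8-fold (log2 fold change 1.48 ± 0.10, adjusted p = 2.14e-09), and Psat1 (log2 fold change 0.73 ± 0.09, adjusted p = 0.000158), Psph (log2 fold change 1.03 ± 0.21, adjusted p = 0.0469), Pck2, the mitochondrial phosphoenolpyruvate carboxykinase (log2 fold change 1.14 ± 0.17, adjusted p = 0.00107), the glycyl-tRNA synthetase gene Gars (log2 fold change 0.55 ± 0.09, adjusted p = 0.00915) and the proline synthesis gene Pycr1 (log2 fold change 2.41 ± 0.51, adjusted p = 0.0469) rose. Prdm1 fell (log2 fold change -0.95 ± 0.12, adjusted p = 0.000158). Among 26 ATF4 and amino acid response genes 3 rose, and 7 when adjusted over the list alone (camera, adjusted p = 3.94e-06). Of 20 osteoclast genes 1 fell, and 9 over the list alone, with a median log2 fold change of -0.32 (camera, adjusted p = 5.93e-07). Nfatc1 had a value of -0.47 ± 0.14, adjusted p = 0.191 and Acp5 of -0.50 ± 0.16, adjusted p = 0.246, but without a filter on low counts both were called (-0.48, adjusted p = 0.00925, and -0.51, adjusted p = 0.00433). The edgeR test called 10 genes raised and 10 lowered, DESeq2 23 and 24, edgeR without a filter on low counts 37 and 103, and with only the compared groups fitted 3 and 7. Leaving out single libraries gave 6, 4 and 9 called genes without full medium replicates 1, 2 and 3, of which 6, 4 and 8 were among the 20. Without proline-free replicate 2 or 3 there were 5, all among the 20, and without proline-free replicate 1 there were 15, of which 10 were. In the same fits Psph lost its call without any 1 of the 6 libraries (adjusted p 0.0634 to 0.232), Pycr1 without any 1 but proline-free replicate 1 (0.152 to 0.237), and Gars without full medium replicate 2 (0.12) or proline-free replicate 3 (0.0634). With only the compared groups fitted Psph, Pycr1 and Gars lost their calls too (adjusted p = 0.164, 0.0966 and 0.094), and with the title number as a block Psph and Pycr1 did (0.0747 for each). Nfatc1 also passed the test without full medium replicate 3 (-0.65, adjusted p = 0.0499). The mitochondrially encoded share was 2.91% ± 0.515 (SD, n = 3).

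**Figure D1:**
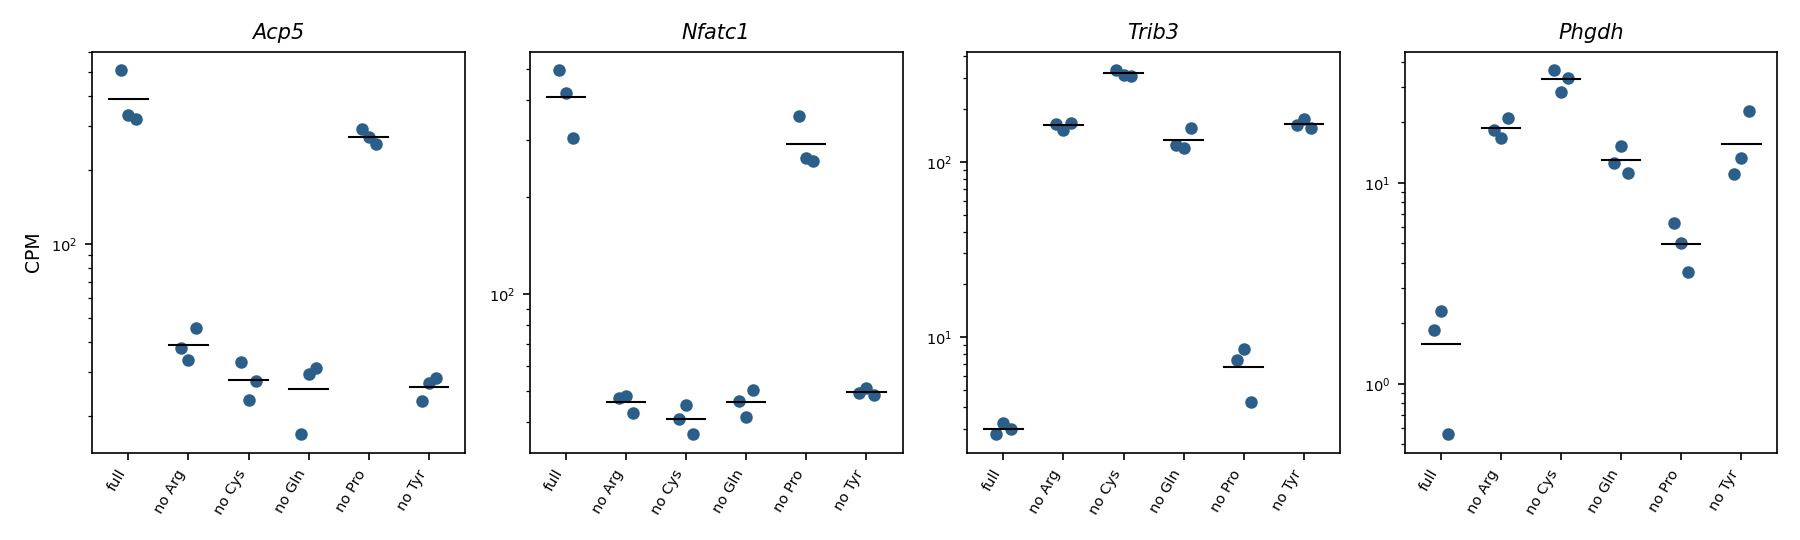
CPM on a log axis for Acp5, Nfatc1, Trib3 and Phgdh in the amino acid experiment. Each point is 1 library, the horizontal bars are means over 3 libraries, and the media are on the horizontal axis. Acp5 and Nfatc1 lie below the full medium libraries in the arginine, cysteine, glutamine and tyrosine free media, and Trib3 and Phgdh lie above them. In the proline free medium Acp5 also lies below and Trib3 and Phgdh above, by smaller distances, while Nfatc1 overlaps the full medium libraries.

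In the inhibitor experiment, RANKL changed bone marrow derived cells from a macrophage profile to an osteoclast profile. Ctsk went from 8.19 ± 4.06 CPM with MCSF alone to 229.8 ± 26.9 CPM with RANKL (n = 4 each; log2 fold change 4.79 ± 0.17, adjusted p = 1.82e-25), and Acp5 from 41.9 ± 8.62 to 634 ± 63 CPM (log2 fold change 3.91 ± 0.14, adjusted p = 1.95e-25). Mmp9 (4.74 ± 0.13), Jdp2 (4.52 ± 0.16), Nfatc1 (2.78 ± 0.10), Src (6.15 ± 0.29), a kinase needed for the resorbing membrane, and Traf1 (5.48 ± 0.17) rose. Of 19 osteoclast genes tested 18 rose and 1 fell, also over the list alone (camera, adjusted p = 1.31e-14). All 6 repressors fell, also over the list alone, with Irf8 at -1.71 ± 0.09 and Mafb at -2.07 ± 0.09 (adjusted p = 1.77e-07). Among 21 macrophage and monocyte genes 19 fell, also over the list alone, including the complement genes C1qa (-3.70 ± 0.11), C1qb (-3.22 ± 0.08) and C1qc (-3.02 ± 0.10), with adjusted p = 5.81e-15. Fcrls, a receptor of macrophages (-6.34 ± 0.23), and Rnase4 (-5.50 ± 0.21) fell most. Genes of oxidative phosphorylation rose in 25 of 37 (26 over the list alone; camera, adjusted p = 1.37e-06), and Shmt2 (1.08 ± 0.12) and Shmt1 (1.32 ± 0.24) rose. Over 9917 genes, edgeR called 2017 raised and 2165 lowered.

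SHIN1 asked what blocking serine hydroxymethyltransferase does to RANKL-treated cells. Osteoclast genes were lower and macrophage genes higher with the inhibitor. Nfatc1 fell 3.14-fold, from 367 ± 22.4 to 117 ± 17.3 CPM (n = 4 each; log2 fold change -1.65 ± 0.10, adjusted p = 2.18e-16). Mmp9 (-1.41 ± 0.10), Jdp2 (-1.69 ± 0.13), Ocstamp (-2.09 ± 0.32), Acp5 (-0.94 ± 0.12) and Ctsk (-0.81 ± 0.12) fell. Osteoclast genes as a list had 13 of 19 that fell and none that rose, also over the list alone (camera, adjusted p = 3.55e-11). Of the repressors 4 of 6 rose, and 6 over the list alone, among them Mafb (1.04 ± 0.09) and Irf8 (0.88 ± 0.09), with adjusted p = 5.8e-07. Macrophage and monocyte genes rose in 13 of 21 (15 over the list alone), with the phagocytic receptor gene Mertk at 1.30 ± 0.14 and C1qa at 0.90 ± 0.11 (camera, adjusted p = 3.48e-08). The thioesterase gene Acot1 (2.72 ± 0.40), the chemokine receptor gene Cxcr4 (1.61 ± 0.15) and the iron exporter gene Slc40a1 (1.51 ± 0.22) were among the most raised. NRF2 and glutathione genes rose in 11 of 20 (13 over the list alone), Gclm by 0.89 ± 0.10 (camera, adjusted p = 1.94e-07, and adjusted p = 0.0819 with an estimated correlation). Of the enzymes of folate metabolism, Shmt2 fell (-0.44 ± 0.12, and -0.31 with adjusted p = 0.0674 without RANKL replicate 4) and Mthfd2 rose (0.41 ± 0.09). The edgeR test called 965 genes raised and 743 lowered.

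Formate given with SHIN1 raised 8 of 19 osteoclast genes against SHIN1 alone, also over the list alone (camera, adjusted p = 3.24e-05). Nfatc1 rose 2.42-fold against SHIN1 (log2 fold change 1.28 ± 0.10, adjusted p = 2.49e-12), with Jdp2 (1.42 ± 0.13), Ocstamp (1.43 ± 0.33), Prdm1 (0.89 ± 0.14) and Mmp9 (0.44 ± 0.11). Acp5 and Ctsk had values of 0.24 ± 0.12, adjusted p = 0.192 and 0.13 ± 0.13, adjusted p = 0.536, so their difference from SHIN1 alone did not pass the test. That of Acp5 did without a filter on low counts (0.26, adjusted p = 0.0359) and without SHIN1 replicate 2 (0.38, adjusted p = 0.0177). Repressors fell in 4 of 6 (5 over the list alone; adjusted p = 0.000104), Irf8 at -0.62 ± 0.09. Macrophage and monocyte genes fell in 12 of 21 (13 over the list alone; adjusted p = 3.24e-05), Mertk at -0.99 ± 0.14. Acot1 (-2.28 ± 0.40) and Cxcr4 (-1.49 ± 0.16) fell. Among aminoacyl-tRNA synthetases 10 of 20 rose (13 over the list alone), with Rars at 0.55 ± 0.11 (camera, adjusted p = 3.59e-07). Neutrophil markers fell in 4 of 11 (7 over the list alone), Camp at -0.72 ± 0.17 (camera, adjusted p = 0.00235, and adjusted p = 0.28 with an estimated correlation). In total 626 genes rose and 743 fell, against 484 and 453 when only these groups were fitted.

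Of the 1708 genes called with SHIN1, 931 (54.5%) were called the opposite way with formate and none the same way. The comparisons share the 4 SHIN1 libraries, whose chance values push them in opposite directions. Independent lists of these sizes would share 72.3 genes raised by SHIN1 and lowered by formate, where 528 were found, and 46.9 in the other direction, where 403 were found. Splitting the SHIN1 libraries 2 and 2, so that no library was used on both sides, gave 349 to 427 genes called opposite ways in the 6 possible ways, with 8 and 12 called the same way in 2 of them and 0 in the other 4. Against RANKL alone, cells given SHIN1 and formate still had lower Mmp9 (log2 fold change -0.97 ± 0.10, adjusted p = 7.11e-08), Acp5 (log2 fold change -0.70 ± 0.12, adjusted p = 0.000998), Ctsk (log2 fold change -0.67 ± 0.12, adjusted p = 0.00276), Nfatc1 (log2 fold change -0.37 ± 0.09, adjusted p = 0.0359) and Car2, a proton-supplying carbonic anhydrase (log2 fold change -1.35 ± 0.33, adjusted p = 0.0411). Pck2 (log2 fold change 1.20 ± 0.21, adjusted p = 0.00221) and Mafb (log2 fold change 0.59 ± 0.09, adjusted p = 0.000691) were higher. Osteoclast genes were lower in 5 of 19 and 11 over the list alone (camera, adjusted p = 2.71e-09). The edgeR test called 45 genes higher and 15 lower, against 123 and 57 by DESeq2, 109 and 73 when only these groups were fitted and 92 and 49 without a filter on low counts, and 1113 had an unadjusted p under 0.05. Single libraries mattered here, since 15, 21 and 16 genes were called without RANKL replicates 1, 2 and 4, and 36, 15 and 29 without SHIN1 and formate replicates 1, 2 and 4. Car2 lost its call without any 1 of the 8 libraries (adjusted p 0.0514 to 0.192) and Nfatc1 without any 1 but RANKL replicate 3 (0.0522 to 0.164).

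**Figure D2:**
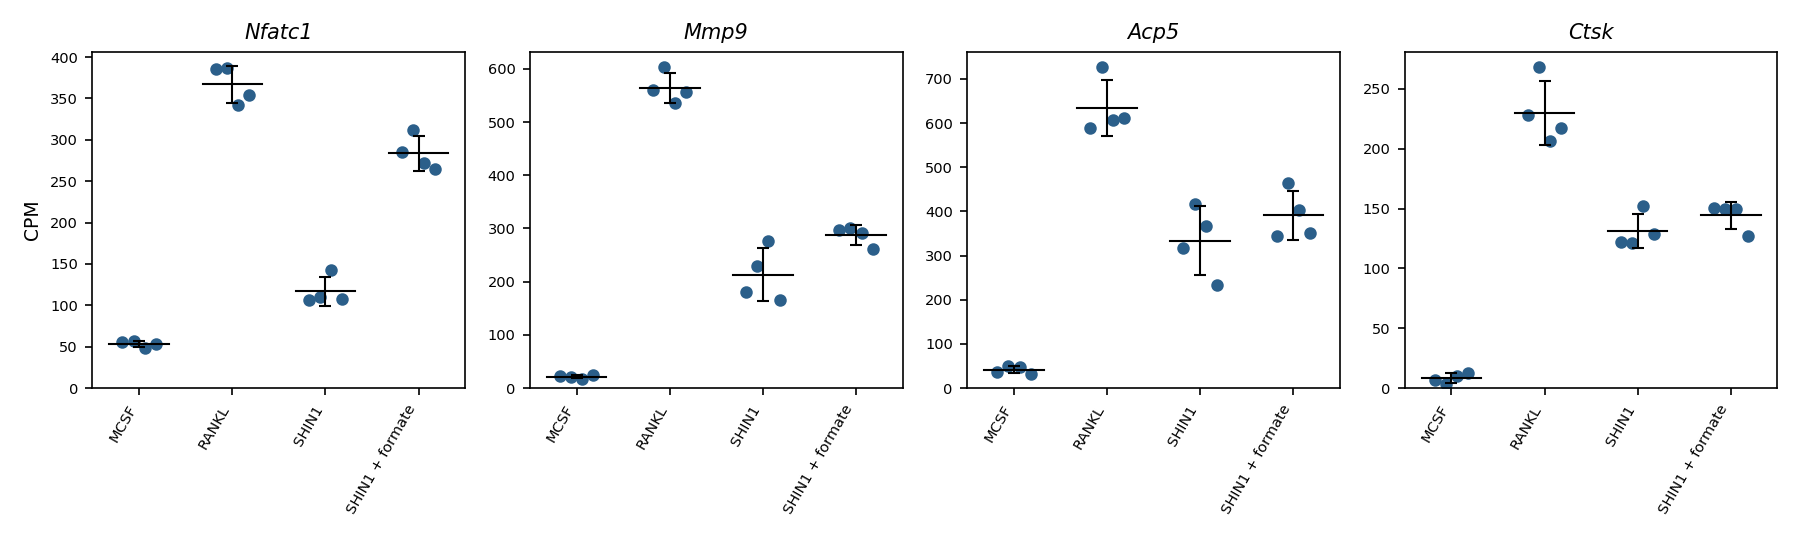
CPM for Nfatc1, Mmp9, Acp5 and Ctsk in the inhibitor experiment, on an axis starting at 0. Each point is 1 library, the bars are means over 4 libraries and the error bars the SD. Nfatc1 with SHIN1 and formate lies between SHIN1 alone and RANKL alone, while Acp5 and Ctsk with SHIN1 and formate lie near their level with SHIN1 alone.

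In the knockout experiment Phgdh reads were few in every library. Phgdh lies on the minus strand of chromosome 3 at 98313170 to 98339990 in GRCm38, as the files give it. Its counts in Ren libraries were 6, 14 and 4 with MCSF, 13, 9 and 6 with RANKL, 22, 19 and 36 without serine and glycine, and 22, 18 and 25 with Pyr. In Ph2 libraries they were 0, 0 and 0 with MCSF, 0, 0 and 1 with RANKL, 2, 6 and 7 without serine and glycine, and 5, 4 and 10 with Pyr. Phgdh was at least 7.18-fold lower in Ph2 with MCSF, against a floor of 3 counts over the group (edgeR, adjusted p = 0.0252), and lower in the serine and glycine free medium (log2 fold change -2.49 ± 0.58, adjusted p = 0.000631) and with Pyr (log2 fold change -1.60 ± 0.57, adjusted p = 0.0187), while with RANKL the adjusted p was 0.0705. The call with MCSF was lost without Ren replicate 2 (adjusted p = 0.16) or Ph2 replicate 1, 2 or 3 (0.0735, 0.157 and 0.0907), and that with Pyr without Ren replicate 1 (0.0586) or Ph2 replicate 1 or 2 (0.0997 and 0.0551). These tags come from the 3' end of the transcript and the labels do not say which part of the gene was edited, so their number does not check the knockout.

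**Figure D3:**
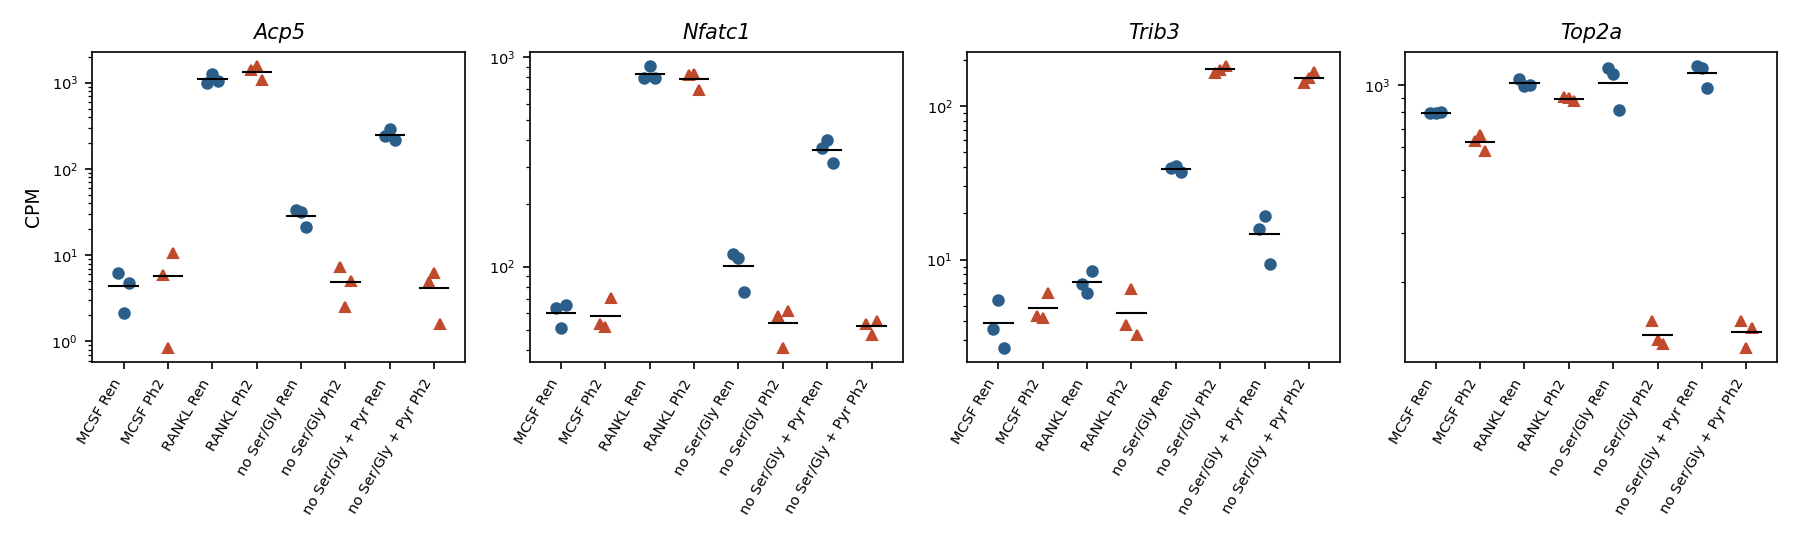
CPM on a log axis for Acp5, Nfatc1, Trib3 and Top2a in the knockout experiment. Each point is 1 library, circles for Ren and triangles for Ph2, and the horizontal bars are means over 3 libraries. In the serine and glycine free medium with Pyr, Acp5 averages 247 CPM in Ren and 4.2 CPM in Ph2.

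RANKL raised osteoclast genes in both genotypes. In Ren cells Acp5 went from 4.37 ± 2.09 to 1102 ± 139.8 CPM (n = 3 each; log2 fold change 7.95 ± 0.23, adjusted p = 3.06e-33), and in Ph2 cells from 5.79 ± 4.91 to 1340 ± 260.3 CPM (log2 fold change 7.92 ± 0.23, adjusted p = 1.15e-33). Ctsk (8.09 ± 0.28 in Ren and 7.44 ± 0.25 in Ph2), Nfatc1 (3.80 ± 0.13 and 3.75 ± 0.13) and Jdp2 (5.61 ± 0.13 and 5.02 ± 0.13) rose in both. Of 19 osteoclast genes 17 rose in Ren (18 over the list alone; camera, adjusted p = 4.45e-14) and 17 in Ph2, also over the list alone (adjusted p = 2.13e-13). Repressors fell in 5 of 6 in each genotype, also over the list alone, Irf8 at -2.76 ± 0.11 in Ren and -2.86 ± 0.11 in Ph2 (adjusted p = 6e-06 and 2.32e-05). The folate enzymes Mthfd2 (1.56 ± 0.09) and Shmt2 (1.49 ± 0.12) and the serine synthesis gene Psat1 (1.15 ± 0.11) rose in Ren. There 10 of 18 serine and one-carbon genes rose (11 over the list alone; camera, adjusted p = 1.06e-05), against 14 in Ph2 (15 over the list alone; adjusted p = 9.21e-07). Neutrophil markers fell in 7 of 7 tested in each genotype, also over the list alone, with S100a9 at -2.79 ± 0.08 in Ren and -2.51 ± 0.08 in Ph2 (adjusted p = 1.02e-07 and 2.86e-07).

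Cholesterol synthesis genes fell in 22 of 23 in Ren and 23 in Ph2, also over the list alone, including Ldlr (-2.08 ± 0.10 in Ren) and Insig1 (-3.84 ± 0.19), with adjusted p = 7.82e-13 and 2.13e-13. In bone marrow derived cells RANKL lowered 12 of 23 and raised 2, or 3 over the list alone (camera, adjusted p = 0.0266, and adjusted p = 0.248 with an estimated correlation). Interferon-stimulated genes rose in 21 of 24 in Ren (22 over the list alone), with Isg15 at 2.66 ± 0.23 and Cxcl10 at 2.82 ± 0.29 (camera, adjusted p = 2.61e-07, and adjusted p = 0.18 with an estimated correlation). RANKL changed 2269 genes upwards and 2375 downwards in Ren, and 2346 and 2491 in Ph2. The test of the difference between genotypes called 0 genes with edgeR and 0 with DESeq2. Of 10102 genes tested 621 had an unadjusted edgeR p under 0.05, where a share of about 0.05 would by chance. Sets of genes raised and lowered by RANKL in bone marrow derived cells, with no member called, were more positive and more negative in Ph2 (median log2 fold change 0.08 and -0.12; camera, adjusted p = 0.00539 and 1.66e-06, and 0.0781 for each with an estimated correlation). With MCSF alone the lowered set was higher in Ph2 (median 0.14, adjusted p = 1.33e-07, and 0.104 with an estimated correlation). In data simulated for the withdrawal by genotype test, 48.3% of 2-fold and 15.7% of 1.5-fold differences were found, so many differences of such sizes would be missed.

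Across the 9587 genes tested in both cell systems, RANKL log2 fold changes in bone marrow derived cells and Ren cells had a Pearson r of 0.693 and a Spearman rho of 0.637, with no shared library. Genes are not independent replicates, so no p is given. Of 2866 genes called in both, 2688 moved the same way, and 1323 were raised in both where independent lists would share 443.9. The 1365 lowered in both compare with 496.2 for independent lists.

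With MCSF alone, the genotypes differed in 32 genes. Apart from Phgdh, Ph2 cells had higher Ednrb, an endothelin receptor gene (log2 fold change 3.01 ± 0.68, adjusted p = 0.0294), Marco, a scavenger receptor gene of macrophages (log2 fold change 0.90 ± 0.11, adjusted p = 7.85e-07), Pltp (0.95 ± 0.21), Apoe (0.80 ± 0.19) and Mrc1 (0.70 ± 0.10), and lower Mki67, a proliferation marker (log2 fold change -0.50 ± 0.12, adjusted p = 0.0294), and Spc24 (-0.70 ± 0.16). Of 20 macrophage and monocyte genes 3 were higher, and 10 over the list alone with 1 lower (camera, adjusted p = 6.53e-06, and adjusted p = 0.0576 with an estimated correlation). Neutrophil markers were higher in 3 of 7, and in 7 over the list alone, with S100a8 at 0.42 ± 0.09 and Ltf at 0.52 ± 0.12 (adjusted p = 0.000187). With RANKL, Ph2 cells had higher S100a9 (log2 fold change 0.63 ± 0.09, adjusted p = 1.68e-05), S100a8 (log2 fold change 0.48 ± 0.10, adjusted p = 0.0138), Marco (log2 fold change 0.62 ± 0.13, adjusted p = 0.0152) and Plxnb2, a plexin gene (log2 fold change 0.63 ± 0.13, adjusted p = 0.0145). They had lower Mir17hg, the host gene of a microRNA cluster (log2 fold change -1.36 ± 0.22, adjusted p = 0.000533). Neutrophil markers were higher in 2 of 7 (4 over the list alone; camera, adjusted p = 1.27e-05). Acp5 had a value of 0.28 ± 0.13, adjusted p = 0.666 and Ctsk of 0.43 ± 0.13, adjusted p = 0.334. The counts of 32 and 6 genes became 105 and 19 with DESeq2 and 96 and 14 without a filter on low counts, and with only the compared groups fitted the first became 139. By edgeR 1008 and 723 of 10102 genes had an unadjusted p under 0.05, where a share of about 0.05 would by chance. Without MCSF Ren replicates 1, 2 and 3 the first count was 18, 10 and 12, without MCSF Ph2 replicates 2 and 3 it was 5 and 13, and the second count was 3 without RANKL Ren replicate 1 or 2. With MCSF, Ednrb and Ltf lost their calls without any 1 of the 6 libraries (adjusted p 0.0775 to 0.202 and 0.0601 to 0.186). Mki67 and Pltp did so without any 1 but Ph2 replicate 1 (0.0916 to 0.172 and 0.081 to 0.127), Apoe and Spc24 without any 1 but Ren replicate 1 (0.0834 to 0.276 and 0.0532 to 0.262), and S100a8 without Ren replicate 2 or 3 or Ph2 replicate 2 (0.0656, 0.0945 and 0.127). With RANKL, Marco lost its call without Ren replicate 1 or 2 or Ph2 replicate 1 or 2 (0.152, 0.181, 0.0742 and 0.0869), Plxnb2 without Ren replicate 1 or 2 or Ph2 replicate 1 or 3 (0.0738, 0.181, 0.0633 and 0.161), and S100a8 without Ren replicate 1 or 2 or Ph2 replicate 2 (0.154, 0.181 and 0.0869).

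Withdrawal of serine and glycine lowered osteoclast genes in Ren cells. Acp5 went from 1102 ± 139.8 to 28.7 ± 6.77 CPM (n = 3 each; log2 fold change -5.28 ± 0.18, adjusted p = 2.84e-29), and Ctsk (-4.05 ± 0.18), Nfatc1 (-3.06 ± 0.12), Atp6v0d2, a proton pump subunit of osteoclasts (-4.03 ± 0.17), and Dcstamp (-4.19 ± 0.50) fell. Of 19 osteoclast genes 16 fell (17 over the list alone; camera, adjusted p = 3.35e-20). All 6 repressors rose, also over the list alone (adjusted p = 1.72e-06), while 16 of 20 macrophage and monocyte genes rose, also over the list alone, Lyz2 by 1.56 ± 0.06 (adjusted p = 2.83e-11). Asns (1.58 ± 0.13), Trib3 (2.45 ± 0.24) and Atf5 (2.21 ± 0.22) rose among 17 of 25 ATF4 and amino acid response genes (18 over the list alone, with 1 lowered; camera, adjusted p = 6.82e-07). Oxidative phosphorylation genes fell in 23 of 37 and rose in 2 (28 lowered over the list alone), Atp5b at -0.77 ± 0.08 (adjusted p = 1.25e-08). Cell cycle genes went both ways, 6 of 27 raised and 6 lowered (7 over the list alone), with Pcna at 0.79 ± 0.11 and Cdc20 at -0.95 ± 0.13. In total 1527 genes rose and 1245 fell.

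In Ph2 cells the withdrawal lowered Acp5 from 1340 ± 260.3 to 4.94 ± 2.38 CPM (n = 3 each; log2 fold change -8.05 ± 0.23, adjusted p = 1.11e-33), and lowered Nfatc1 (-3.87 ± 0.13), Jdp2 (-3.92 ± 0.11) and Ctsk (-4.72 ± 0.18). Of 19 osteoclast genes 16 fell and 1 rose, also over the list alone (camera, adjusted p = 1.33e-11). Trib3 rose 39.4-fold (log2 fold change 5.30 ± 0.23, adjusted p = 5.07e-26) and Ddit3 by 3.06 ± 0.16. In all, 17 of 25 ATF4 and amino acid response genes rose and 2 fell, also over the list alone (adjusted p = 6.51e-05). All 27 cell cycle genes fell, also over the list alone, with Top2a at -2.77 ± 0.10 and Rrm1 at -2.16 ± 0.11 (adjusted p = 1.14e-21). Serine and one-carbon genes fell in 14 of 18 and rose in 2, also over the list alone, with Shmt1 at -3.41 ± 0.38, Dhfr at -1.90 ± 0.17 and Psph at -0.97 ± 0.33 (camera, adjusted p = 0.000122). Psph lost its call without serine and glycine free Ph2 replicate 2 (-0.82, adjusted p = 0.0662). Neutrophil markers fell in 7 of 7, also over the list alone, S100a9 at -2.46 ± 0.10 (adjusted p = 3.55e-07). In total 2545 genes rose and 2458 fell.

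The test of the difference between genotypes called 1694 genes for the withdrawal, 739 with a more positive change in Ph2 and 955 with a more negative one. The change of cell cycle genes was more negative in Ph2 in all 27 tested, also over the list alone, with Top2a at log2 fold change -2.77 ± 0.13, adjusted p = 3.38e-23 and Birc5 at -3.01 ± 0.16 (camera, adjusted p = 3.55e-44). Serine and one-carbon genes differed in the same direction in 12 of 18 (13 over the list alone), with Dhfr at -2.38 ± 0.23 and Psat1 at log2 fold change -1.25 ± 0.15, adjusted p = 7.3e-09 (adjusted p = 1.16e-08), and neutrophil markers in 7 of 7, also over the list alone, with S100a9 at -2.53 ± 0.13 (adjusted p = 2.27e-12). Trib3 (log2 fold change 2.85 ± 0.39, adjusted p = 1.05e-07) and Ddit3 (2.42 ± 0.24) rose further in Ph2. Of the osteoclast genes 8 of 19 had a more negative change in Ph2 (9 over the list alone), with Acp5 at log2 fold change -2.77 ± 0.36, adjusted p = 3.96e-08 and Jdp2 at -1.54 ± 0.15 (camera, adjusted p = 0.00813, and adjusted p = 0.129 with an estimated correlation). Compared directly in that medium, Ph2 cells had lower Top2a (-2.95 ± 0.10), S100a9 (-1.90 ± 0.10), Psat1 (-1.48 ± 0.11) and Acp5 (-2.49 ± 0.34) than Ren cells. They had higher Trib3 (2.15 ± 0.17), Ddit3 (2.24 ± 0.15), Gdf15 (2.72 ± 0.34) and Irf8 (0.92 ± 0.10). Ctsk had a value of -0.24 ± 0.25, adjusted p = 0.509. In this comparison all 27 cell cycle genes (adjusted p = 1.04e-37), 14 of 18 serine and one-carbon genes (adjusted p = 1.5e-09) and 7 of 7 neutrophil markers (adjusted p = 2.2e-09) were lower in Ph2, each also over the list alone. The 14 include Phgdh itself, the gene that the Ph2 label names as knocked out. In contrast, 13 of 16 subunits of the vacuolar proton pump were higher, also over the list alone, with Atp6v1a at 0.56 ± 0.06 (adjusted p = 4.51e-07). The edgeR test called 1583 genes higher and 1603 lower.

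Pyr added to the serine and glycine free medium raised osteoclast genes in Ren cells. Acp5 rose 8.7-fold, from 28.7 ± 6.77 to 247 ± 39.2 CPM (n = 3 each; log2 fold change 3.12 ± 0.19, adjusted p = 2.88e-18), with Ctsk (2.60 ± 0.19), Nfatc1 (1.85 ± 0.12), Dcstamp (2.90 ± 0.53) and Jdp2 (1.46 ± 0.10). Osteoclast genes rose in 16 of 19, also over the list alone (camera, adjusted p = 1.22e-18). Repressors fell in 4 of 6 (5 over the list alone), Irf8 at -0.92 ± 0.11 (adjusted p = 6.22e-05). ATF4 and amino acid response genes fell in 7 of 25 (11 over the list alone, with 1 raised), Trib3 at -1.44 ± 0.20 and Asns at -0.72 ± 0.12 (adjusted p = 0.000192). Interferon-stimulated genes rose in 21 of 24 (23 over the list alone), with Cxcl10 at 1.44 ± 0.22 (adjusted p = 3.17e-11, and adjusted p = 0.114 with an estimated correlation). In total 699 genes rose and 843 fell.

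In Ph2 cells Pyr changed 2 genes by the edgeR test, Fancd2, a DNA repair gene, which rose (log2 fold change 2.09 ± 0.41, adjusted p = 0.0235, chosen after its values were seen), and Fos, an immediate early gene, which fell (log2 fold change -0.72 ± 0.11, adjusted p = 0.000218). By edgeR 576 of 10102 genes had an unadjusted p under 0.05, where a share of about 0.05 would by chance. DESeq2 called 4 genes, 7 were called without a filter on low counts, and 1 was called without serine and glycine free Ph2 replicate 1 or 2, or Pyr Ph2 replicate 3. In those fits Fancd2 had adjusted p = 0.0588, 0.474 and 0.595, and it had adjusted p = 0.358 when only the compared groups were fitted. Acp5 was at 4.94 ± 2.38 CPM without and 4.2 ± 2.35 CPM with Pyr (-0.33 ± 0.52, adjusted p = 0.968), a value near 0 that became 0.09 without serine and glycine free Ph2 replicate 1 and 0.10 without Pyr Ph2 replicate 3. None of 19 osteoclast genes was called, also over the list alone, with a median log2 fold change of -0.01 and a mean of 0.04. No cell cycle gene was called, but their median was 0.18 and 3 of 27 rose over the list alone (camera, adjusted p = 5.05e-06, and adjusted p = 0.0548 with an estimated correlation). The difference between genotypes was called in 474 genes, 311 more positive and 163 more negative in Ph2 (407 and 280 by DESeq2), and in 313 without serine and glycine free Ren replicate 3. It was more negative in 12 of 19 osteoclast genes (14 over the list alone), with Acp5 at log2 fold change -3.45 ± 0.57, adjusted p = 6.7e-05, Ctsk at -1.96 ± 0.31, Nfatc1 at -1.89 ± 0.20 and Jdp2 at -1.77 ± 0.16 (camera, adjusted p = 8.36e-17), and more positive for Irf8 (0.85 ± 0.14) and Trib3 (1.26 ± 0.25).

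With Pyr, Ph2 and Ren cells differed in 4693 genes, 2424 higher and 2269 lower in Ph2. Acp5 was 61.3-fold lower (log2 fold change -5.94 ± 0.26, adjusted p = 1.59e-25), Nfatc1 was lower (-2.78 ± 0.13), and so were 15 of 19 osteoclast genes with 2 higher, also over the list alone (camera, adjusted p = 1.01e-07). All 27 cell cycle genes were lower, also over the list alone, with Top2a at -3.02 ± 0.10 (adjusted p = 1.5e-24), as were 14 of 18 serine and one-carbon genes with 1 higher (lower in 15 over the list alone; adjusted p = 1.02e-06) and 7 of 7 neutrophil markers, also over the list alone, with S100a9 at -1.49 ± 0.10 (adjusted p = 2.69e-05). The 14 serine and one-carbon genes include Phgdh itself. Trib3 (3.41 ± 0.19), Gdf15 (3.77 ± 0.40) and Irf8 (1.77 ± 0.10) were higher.

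Gene sets taken from another table share no library with the comparison. Of the 200 genes most clearly raised by RANKL in bone marrow derived cells, 198 were tested in the amino acid table, and 150 fell without arginine, 167 without cysteine, 161 without glutamine, 150 without tyrosine and 1 without proline (camera, adjusted p from 3.98e-37 without arginine to 7.84e-06 without proline). In the knockout experiment 193 were tested, of which 114 fell on withdrawal of serine and glycine in Ren and 144 in Ph2, and 88 rose with Pyr in Ren (camera, adjusted p = 7.48e-21). With Pyr in Ph2 none of them rose and 1 fell, while the raised set as a whole tested up (median log2 fold change 0.04) and the lowered set down (-0.03), each with adjusted p = 0.0424. These became 0.375 and 0.442 with an estimated correlation, and 0.276 and 0.0693 with sets of 100 genes. Of the 199 tested genes raised by RANKL in Ren cells, 134 fell with SHIN1 and 104 rose when formate was added (camera, adjusted p = 7.95e-35 and 2.65e-26). Sets lowered by RANKL moved the opposite way, 119 of 196 rising with SHIN1 and 90 falling with formate (adjusted p = 1.32e-31 and 1.47e-19). With SHIN1 and formate against RANKL, 5 of the raised set were lower and 1 higher (adjusted p = 3.57e-06, and adjusted p = 0.0636 with an estimated correlation), and 12 of the lowered set were higher and 1 lower (adjusted p = 9e-12 and 0.000881).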

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

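The splits of the samples, the test of osteoclast genes in Ph2 cells with RANKL and the test of Phgdh ratios were chosen only after the results were seen.

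The effect of serine and glycine withdrawal differed by genotype in 1694 genes, by a test of the difference itself. The log2 fold changes of the difference were -2.77 for Acp5, -3.01 for Birc5, 2.42 for Ddit3, -2.38 for Dhfr, -1.54 for Jdp2, -1.25 for Psat1, -2.53 for S100a9, -2.77 for Top2a and 2.85 for Trib3. Medians over lists were -2.31 for cell cycle genes, -2.53 for neutrophil markers, -1.18 for serine synthesis and folate one-carbon genes, -0.65 for purine synthesis genes and -0.66 for osteoclast genes, whose list test did not pass with an estimated correlation (adjusted p = 0.129). The effect of Pyr differed by genotype in 474 genes, with -3.45 for Acp5, -1.96 for Ctsk, 0.85 for Irf8, -1.77 for Jdp2, -1.89 for Nfatc1, 1.26 for Trib3 and a median of -1.74 for osteoclast genes.

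In the groups of 4 libraries, 1 library stood apart from the other 3 by a gap, relative to the range, over Dixon's critical value in 9 of 116 groups of values tested, where chance gives about 5%. Total counts were 2429481 in MCSF replicate 1, 3686414 in RANKL replicate 4 and 2717678 in SHIN1 and formate replicate 4. Among genes, Cxcr4 was at 45.3 CPM in MCSF replicate 2, Irf8 at 395.6 CPM in MCSF replicate 4, Acp5 at 727.4 CPM in RANKL replicate 2, C1qc at 194.7 CPM in SHIN1 replicate 4, Nfatc1 at 142.9 CPM in SHIN1 replicate 3 and Ctsk at 127 CPM in SHIN1 and formate replicate 4.

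Pyr raised osteoclast genes in Ren cells, while none was called in Ph2 cells. The Ph2 libraries did not have a lower depth as a group. Their totals were 2285633 to 2756140 without Pyr and 1709951 to 2810655 with it, against 1871479 to 2388320 and 2150553 to 3039130 in Ren. Ren libraries thinned to the lowest Ph2 total of 1709951 still gave a median of 1407 called genes (1379 to 1421 in 5 draws). The choice between TMM and RLE is argued against as the cause, since 13 osteoclast genes were more negative in Ph2 by genotype under RLE size factors. Both methods assume that most genes do not change, so an error common to both was not tested. A lower osteoclast programme of the Ph2 line in any medium is argued against by 0 osteoclast genes called lower in Ph2 with RANKL by edgeR, adjusted over the list alone. Over all 10102 genes, that comparison had 723 with an unadjusted p under 0.05, where a share of about 0.05 would by chance. A dependence on Phgdh may be a candidate explanation. A difference between the lines that arose with their making and shows only without serine and glycine stays open, since each genotype is given as 1 line.

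Phgdh reads were found in Ph2 libraries without serine and glycine. Reads or cells of the Ren kind in the Ph2 samples might give them, in which case few genes would lie below the Phgdh ratio of Ph2 to Ren. A gene was counted as below only where the upper limit of its 95% counting interval was under the lower limit for Phgdh. Genes with a ratio merely under that of Phgdh were not counted. The Phgdh ratio was 0.169 (95% counting interval 0.0905 to 0.297) without serine and glycine, where 4 of 7986 genes were counted as below. With Pyr it was 0.329 (0.186 to 0.555), and 98 of 7974 genes were counted as below. Acp5 had a ratio of 0.178 (0.121 to 0.256) without Pyr, not under the Phgdh ratio, and of 0.0162 (0.0107 to 0.0237) with Pyr, which is under it. Reads or cells of the Ren kind would bring every gene to at least the share they give Phgdh. With Pyr, the 98 genes below the ratio, 5 of them osteoclast genes, argue against them as the only source of the Phgdh reads. Without Pyr, where 4 genes lay below, transcripts from an edited gene and reads of the Ren kind cannot be told apart. The test had asked for an answer in both media, which differed, and 15 and 19 Phgdh counts are few.

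For each comparison of 3 against 3 libraries there are 10 splits of the samples, too few for a share under 5%. The real count and the highest of the other splits were 3118 and 0 without arginine, 5587 and 0 without cysteine, 4977 and 0 without glutamine, 20 and 6 without proline, 3406 and 0 without tyrosine, 4644 and 0 for RANKL in Ren, and 4837 and 0 for RANKL in Ph2. They were 32 and 1 for Ph2 against Ren with MCSF, 3186 and 0 without serine and glycine, 4693 and 1 with Pyr, 2772 and 0 for withdrawal in Ren, 5003 and 0 in Ph2, 1542 and 0 for Pyr in Ren, and 2 and 0 in Ph2, in each of these with 1 split as large, the real one. For Ph2 against Ren with RANKL 3 of 10 splits gave at least the real 6 genes, the highest other giving 13.

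With 4 against 4 libraries there are 35 splits, of which only the real one was as large in each comparison. The counts were 4182 genes for RANKL in bone marrow derived cells (highest other 0), 1708 for SHIN1 (highest other 1), 1369 for formate (highest other 87) and 60 for SHIN1 with formate against RANKL (highest other 1). A share of 1 in 35 is the smallest these splits can give. Libraries of a group may be technical, so the splits do not exclude a chance difference between cultures. By genotype 100 splits were drawn. For RANKL the real count is 0, which every split reaches (highest other 49), so they test nothing there. Of the splits 9 gave at least the 1694 genes of withdrawal (highest other 2193) and 14 at least the 474 of Pyr (highest other 5303). Those as large each kept a genotype whole in a serine and glycine free medium. They therefore still carry the difference between genotypes in that medium and are not chance draws. The 85 and 82 splits that kept a genotype whole in no medium gave at most 0 and 1 genes. Such mixing puts the difference between genotypes into the spread within groups, which lowers these counts in advance. The numbers 9 and 14 thus neither exclude chance nor speak for it.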

How the results depend on the processing

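Leaving out libraries for the correlation between systems and for the formate overlap was chosen after seeing the data, and the other alternatives were planned. Of the total counts of called genes per comparison, those for arginine, cysteine, glutamine, tyrosine, RANKL in each system, SHIN1, formate, the withdrawals, Pyr in Ren, the comparisons by genotype and Ph2 against Ren in both serine and glycine free media stayed within 1.5 times under every alternative that left out no replicate. By direction, the lowered genes moved further for formate, from 743 to 453 with only the compared groups fitted, and for Pyr by genotype, from 163 to 280 with DESeq2. RLE size factors moved no count of called genes by more than that.

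Without a filter on low counts, 140 genes were called for proline, 141 for SHIN1 with formate against RANKL, 96 for Ph2 against Ren with MCSF, 14 with RANKL and 7 for Pyr in Ph2. DESeq2 called 47, 180, 105, 19 and 4. With only the compared groups fitted the first 3 became 10, 182 and 139, and with the title number as a block proline gave 6, though the numbers do not pair the libraries. Of 455 list tests 194 passed with the preset correlation and 105 with an estimated correlation. The correlation between systems was 0.853 over genes called in both, a choice that removes genes near 0, and the formate overlap was 463 at an adjusted p under 0.01. Otherwise the cause was not tested.

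With 1 library left out, which in a group of 3 leaves 2, counts were 2413 to 2693 for arginine, 5030 to 5271 for cysteine, 4370 to 4726 for glutamine, 4 to 15 for proline, 2823 to 3046 for tyrosine, 3844 to 3916 for RANKL in bone marrow derived cells, 1334 to 1690 for SHIN1, 944 to 1524 for formate and 15 to 46 for SHIN1 with formate against RANKL. In the knockout table they were 4203 to 4306 for RANKL in Ren and 4419 to 4552 in Ph2, 5 to 29 for Ph2 against Ren with MCSF, 3 to 8 with RANKL, 2636 to 2940 without serine and glycine and 4171 to 4393 with Pyr. Withdrawal gave 2252 to 2475 in Ren and 4554 to 4677 in Ph2, Pyr 1081 to 1289 in Ren and 1 to 3 in Ph2. By genotype they were 0 for RANKL (edgeR), 1463 to 1667 for withdrawal and 313 to 468 for Pyr, the lowest without serine and glycine free Ren replicate 3. The correlation was 0.675 to 0.693 and the overlap 679 to 972.

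Of 2601 values of 234 results, each a named gene in 1 comparison, 2502 kept their direction and side of the threshold, 92 lost their call, 5 gained one and 2 changed sign, both with 1 library left out. The sign changes were those of Acp5 for Pyr in Ph2, never called, at 0.09 and 0.10 without serine and glycine free Ph2 replicate 1 and Pyr Ph2 replicate 3 (range -0.65 to 0.10). Of the lost calls 86 came with 1 library left out. In the simulated data, with 200 genes changed per set, many changes of 1.5-fold were missed, and in the test by genotype many of 2-fold. Comparisons with far more changed genes may miss fewer.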

Other observations

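The tests of lists in this part were planned, and the genes and lists described first were picked after their values were seen.

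Purine synthesis genes, whose pathway takes 1-carbon units from formyl-folate, were called as a list in 11 of 22 comparisons, up in 4 and down in 7. Those described here are RANKL in Ren cells, withdrawal of serine and glycine in Ph2 cells and by genotype, and cysteine withdrawal. RANKL raised 7 of 14 in Ren cells, also Impdh2 (1.95 ± 0.16) and Gart (1.35 ± 0.14), with adjusted p = 0.00476 (camera). In Ph2 cells withdrawal of serine and glycine lowered 10 of 14 and raised 1 (adjusted p = 0.000162), and the difference by genotype was more negative in 9 of 14 (adjusted p = 3.37e-05). Without cysteine 9 of 13 fell, with Pfas at -2.08 ± 0.14 (adjusted p = 0.00296).

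Interferon-stimulated genes were lower in Ph2 than in Ren cells in 18 of 24 without serine and glycine (camera, adjusted p = 1.26e-06, and adjusted p = 0.254 with an estimated correlation) and in 23 of 24 with Pyr (adjusted p = 6.07e-10, and adjusted p = 0.119 with an estimated correlation). Unfolded protein response genes fell with RANKL in 8 of 12 in bone marrow derived cells and 8 of 12 in Ren cells (adjusted p = 0.000219 and 0.00057).

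Over the 22 comparisons 455 list tests were made. An adjusted p under 0.05 was reached by 194 of the 455 with the preset correlation and by 105 of the 455 with an estimated correlation. Lists tested in 22 comparisons were called in 17 for osteoclast genes (16 with an estimated correlation), 17 for repressors of osteoclast formation (11), 19 for macrophage and monocyte genes (9), 11 for serine synthesis and folate one-carbon genes (9), 12 for ATF4 and amino acid response genes (11), 11 for aminoacyl-tRNA synthetases (5), 5 for cholesterol synthesis genes (2), 15 for NRF2 and glutathione genes (5), 14 for cell cycle genes (8), 2 for p53 targets (0), 9 for interferon-stimulated genes (0), 0 for inflammatory genes (0), 16 for nuclear-encoded oxidative phosphorylation genes (6), 4 for glycolysis genes (0), 11 for purine synthesis genes (10), 1 for methyl cycle and chromatin methylation genes (0), 4 for unfolded protein response genes (2), 8 for V-ATPase genes (3) and 13 for neutrophil markers (8). Mitochondrially encoded genes were called in 1 of 5 (0), dendritic cell markers in 4 of 9 (0), progenitor genes in 0 of 5 (0) and sex-linked genes in 0 of 18 (0). Markers of B cells, T and NK cells, erythroid cells, stromal cells and osteoblasts, and mast cells and basophils had fewer than 3 tested members in each table and were not tested.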
